A study of Bos taurus with 8 samples.

How the data were processed

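Gene expression was measured in bovine embryos produced in vitro. Per the labels' protocols, medium alone or colony-stimulating factor 2 (CSF2) was added to the culture drops on day 5 after insemination, to a final 0 or 10 ng/ml. Morulae and early blastocysts were collected 24 h later, on day 6, and frozen in pools of 50 embryos. There were 4 pools per treatment, drawn from 6 rounds of in vitro production. The labels do not say which round a pool came from. Total RNA was amplified into single-stranded cDNA, labelled with Cy3 or Cy5, and hybridised to Agilent two-colour arrays. In 2 of the 4 numbers carried by the sample titles, the control pool was labelled with Cy3 and the CSF2 pool with Cy5, and in the other two the dyes were switched.

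The deposited table holds 1 column per pool and 21475 probes, and all 8 columns were used. Images were quantified by the authors with Agilent Feature Extraction 9.5, per the submitters' processing notes. The background correction, the averaging of spots and the normalization are not given in the sources used here. The deposited values were taken as log2 signal: they ran from 1.08 to 16.1, no value was missing, and the top lies close to the limit of a 16-bit scanner. The log base is not stated, so each fold below rests on that reading. When each column was sorted, values of the same rank differed between columns by a median of 0.0149, with a largest gap of 0.185. The columns had therefore been brought to nearly one distribution before deposit, and a shift common to most probes would have been removed with it. Detection flags and background levels were not used here, so a probe of low signal cannot be called absent. Between 11.5% and 11.9% of the probes of each sample lay below a log2 signal of 2.

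The table identifies probes by Agilent probe IDs alone. Of 37063 genes in the RefSeq gene table for cattle used here, 0 rows carried such an ID. No probe was therefore given a gene name or a genome position, and the 27 gene lists fixed before the data were examined (signalling, apoptosis, cell lineage and other cell type markers, metabolism) could not be tested. The rule for named genes, also fixed beforehand, was applied to probes: the smallest unadjusted p among probes with at least a 1.5-fold difference and the same sign in all 4 numbers. It was limited to 2 probes per direction because a bare probe ID carries no biology.

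Each channel was treated as 1 sample, after the design text, which describes a dye switch and no use of ratios. The values were fitted as deposited, without a filter, with limma 3.58.1 in R 4.3.3. The model held treatment and dye as fixed terms and the number in the sample title as a random block (duplicateCorrelation, consensus correlation 0.296), followed by eBayes. Tests were two-sided, and p-values were adjusted over the 21475 probes by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 5 residual degrees of freedom per probe and a prior worth 1.53 more. All differences are CSF2 minus control. A looser count, of probes at an unadjusted p under 0.05 with at least a 1.5-fold difference, was also fixed beforehand. The count of probes whose 95% interval lay within 1.5-fold either way was added after the data were seen.

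The numbers were checked as pairs. The deviations of same-numbered control and CSF2 pools from their treatment and dye means correlated at 0.377 to 0.430 in all 4 numbers. Taking out these means alone gives a correlation of 0.2 between 2 samples that differ in both treatment and dye, as same-numbered pools do. The 4 other combinations that differ in both correlated at -0.0478 to 0.0647. The numbers were therefore kept as pairs. The labels name the pools as separate groups of embryos, so the tests measure the spread between pools. Precision is limited by there being 4 pools per group.

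The fit was tested on simulated data with the 21475 probes' own means, moderated variances and dye differences, with 200 changed probes in each of 3 simulations. Of the probes above the median signal, 73.2% of those changed 2-fold and 100% of those changed 4-fold were called with the right sign. Of those below the median, 41.5% and 63.8% were called. These rates hold for 200 changed probes among the 21475. With fewer changed probes the Benjamini-Hochberg cutoff is stricter, and a smaller share would be called. False calls made up 6.17% of all calls, unchanged probes fell under an unadjusted p of 0.05 in 5.63% of cases, and the block correlation was found at 0.360 where 0.296 had been put in. The simulation gives every probe the same block correlation, which real probes need not share. It also draws the probes independently of each other.

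Alternatives changed the block, the dye term, the normalization (quantile, median centring, cyclic loess), the filter on dim probes, a floor on low values, the variance prior and the moderation. Each number and each single sample was also left out in turn. Averaging several probes of a gene was planned and could not be run without gene names.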

Results

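RNA levels were compared between day 6 bovine embryos that had been exposed to CSF2 for 24 h and embryos that had received medium alone. CSF2, also known as granulocyte-macrophage colony-stimulating factor, is a cytokine. The series asks whether it changes the transcriptome of the preimplantation embryo. Each group held 4 pools of 50 morulae and early blastocysts. Each pool was read in 1 channel of a two-colour array, with the dyes switched between numbers 1 and 3 and numbers 2 and 4. The 8 samples gave a value for all 21475 probes, with medians between 7.77 and 7.79 on the log2 scale. The probes are reported without gene names, because the table pairs none with its IDs.

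The number shared by a control and a CSF2 pool separated the samples more than treatment or dye did. Between pools of different numbers, correlations over all probes ran from 0.977 to 0.985 for a control against a CSF2 pool (12 combinations) and from 0.979 to 0.985 within a treatment (12 combinations). Between the control and the CSF2 pool of one number they ran from 0.983 to 0.988 (4 combinations). These correlations are across probes, which are not independent replicates, and the wide range of signal between probes holds them near 1. The number accounted for 98.0% of the scores on the first principal component, 98.9% on the second and 88.1% on the third, against 1.76%, 0.623% and 0.535% for treatment. Treatment accounted for 67.1% of the fifth component, which held 12.8% of the variance. Over all probes, the numbers took 52.6% of the sum of squares with 3 of 7 degrees of freedom, for which chance gives 42.9%. The 47.4% left within the numbers had 4 degrees of freedom, an average of 11.9% for each. Of this CSF2 took 12.05% and dye 12.88%, each with 1 degree of freedom.

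**Figure D1:**
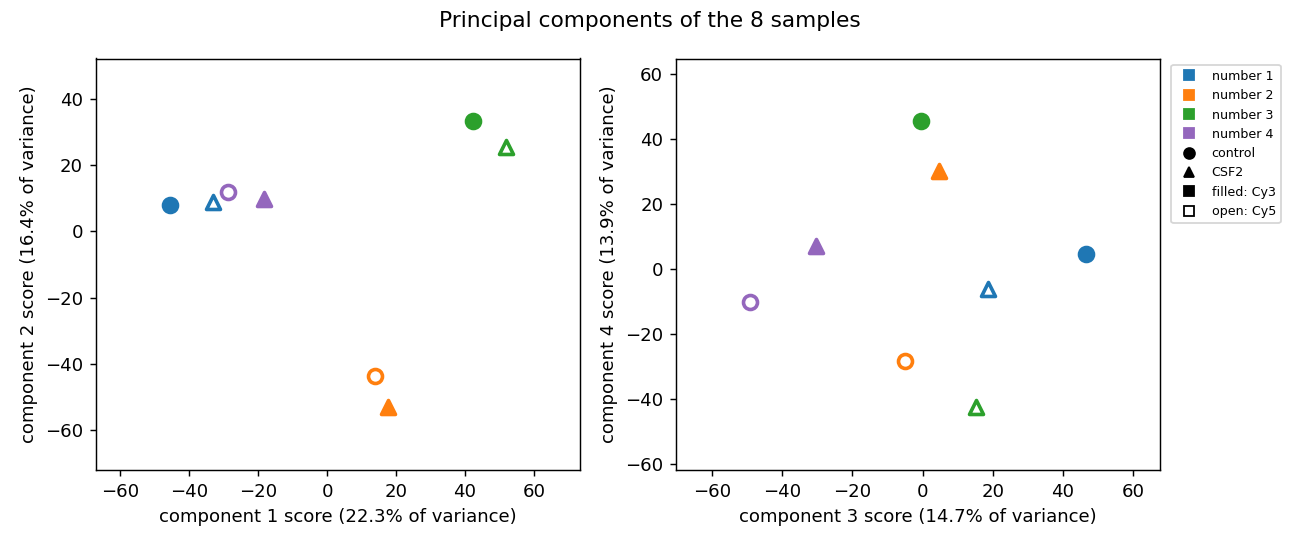
Scores of the 8 samples on principal components 1 and 2 (left) and 3 and 4 (right) of the log2 signal of 21475 probes; colour marks the number, shape the treatment and fill the dye. The control and CSF2 pools of a number lie near each other on components 1 and 2, where numbers 1 and 4 adjoin, and which hold 22.3% and 16.4% of the variance.

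No probe passed the test for a difference between CSF2 and control embryos: 0 of 21475 reached an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.167. An ordinary test per probe without moderation also called 0. At an unadjusted p under 0.05 there were 1795 probes (8.36%), where a 5% share would be 1074. Of these, 901 had higher values with CSF2 and 894 lower. At least a 1.5-fold difference was shown by 571 of the 1795, of which 285 were higher and 286 lower with CSF2. These 2 looser counts depended on the pairing: without the block on the number they were 924 and 349, so that the first lay below 1074. Treatment varies within the numbers, so a fit without the block counts the spread between numbers as error. Such a fit is stricter where same-numbered pools deviate together. With the number as a fixed block the 2 counts were 1291 and 565. Without both pools of number 4 the counts were 3165 and 1207. The 1.5-fold count was 1045 without number 1, 953 without number 3, and 348 in the ordinary test per probe.

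The order of the pools within single probes was also counted. In 606 probes (2.82%) all 4 CSF2 pools lay above or all lay below the 4 control pools, where free exchange of the 8 pools gives 2.86%. Because the numbers are pairs, that share is not the chance level of this design. Leaving aside the one that equals dye, the 6 other assignments of treatment within the numbers gave 247 to 726 such probes. Of these assignments 1 reached 606, and it reversed treatment in number 4 alone. It therefore kept the real labels in the other numbers, and with them part of any CSF2 response. The assignments that reversed numbers 2 and 3, or 3 and 4, mixed treatment evenly and gave 247 and 408. The split by dye gave 906. CSF2 was the higher group in 282 of the 606 probes and the lower in 324. The difference between the CSF2 and the control pool had the same sign in all 4 numbers in 3249 probes (15.1%), where independent signs give 12.5%. Of these probes, 1408 were higher and 1841 lower with CSF2. This count was not compared with the other assignments within the numbers, so its distance from 12.5% cannot be judged. The CSF2 minus control differences of one number correlated with those of another number at -0.0406 to 0.0702 across probes. Where the dyes were the same way round they correlated at 0.0340 (numbers 1 and 3) and 0.0702 (numbers 2 and 4). Where the dyes were switched they correlated at -0.0406 to 0.0187. Each difference also holds a dye difference, so the range alone does not measure agreement on CSF2.

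The data bounded the size of the CSF2 effect well for bright probes and poorly for dim ones. For 11646 probes (54.2%) the 95% interval of the difference lay within 1.5-fold either way, and for 16667 (77.6%) it lay within 2-fold. These intervals rest on a common block correlation and would be too narrow if the p-values of the fit are too small. With the number as a fixed block, 10909 probes were bounded within 1.5-fold. Since the columns had been made nearly alike in distribution, the bounds hold relative to most other probes. Of the 11646, 1778 lay in the lowest quartile of signal. Near the lower end of the scale a narrow interval bounds the signal and need not bound the RNA, since detection was not assessed. In the highest quartile of signal, 4999 of 5369 probes (93.1%) were bounded within 1.5-fold, with a median interval of 1.16-fold to either side. In the third quartile this held for 61.8% of probes, in the second for 28.9% and in the lowest for 33.1%, where the median interval reached 1.53-fold to either side. The median SD of the differences between numbers was 0.186 (log2, n = 4) in the highest quartile and 0.537 in the lowest. Among the 571 probes with an unadjusted p under 0.05 and at least a 1.5-fold difference, 502 lay below the median signal and 69 above it. The highest quartile held 1 such probe, with lower values after CSF2.

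**Figure D2:**
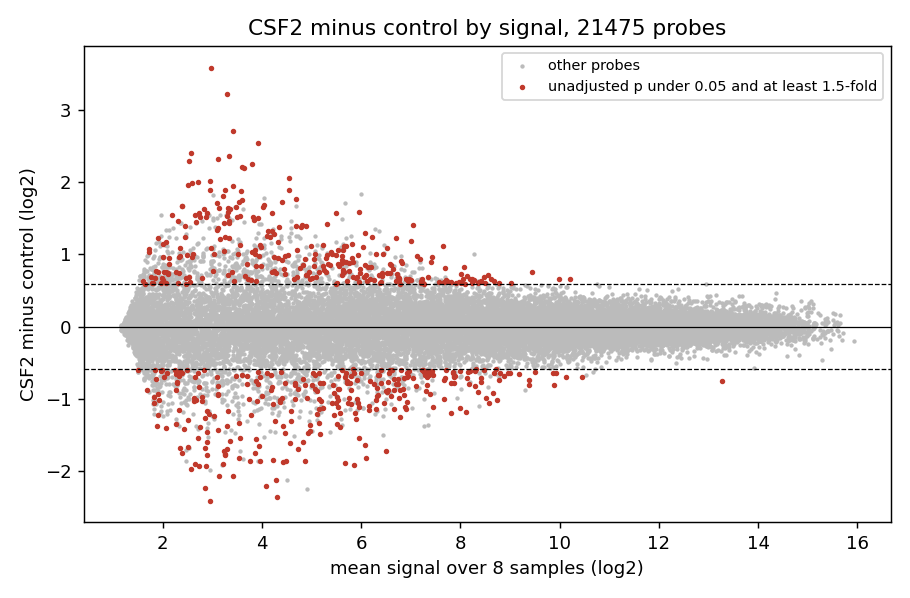
CSF2 minus control difference (log2, vertical) of each of 21475 probes against its mean log2 signal over the 8 samples (horizontal); red points are the 571 probes with an unadjusted p under 0.05 and at least a 1.5-fold difference, and dashed lines mark 1.5-fold. The differences narrow above the median signal, and 502 of the red points lie below the median signal.

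The leading probes had separate groups but did not pass the adjusted threshold. Probe A_73_101137 had a log2 signal of 1.69 ± 0.39 (SD, n = 4) in control and 4.91 ± 0.82 in CSF2 pools. Probe A_73_113866 had 5.16 ± 0.31 in control and 6.75 ± 0.23 in CSF2 pools, a difference of 1.58 (SE 0.17) or 2.99-fold. Probe A_73_106087 had 6.80 ± 0.17 in control and 5.79 ± 0.20 in CSF2 pools, a difference of -1.01 (SE 0.09), which is 2.02-fold lower. Probe A_73_101004 had 3.62 ± 0.29 in control and 2.17 ± 0.21 in CSF2 pools. The control values of A_73_101137 and the CSF2 values of A_73_101004 lay near the lower end of the scale, where the size of a difference depends on the background correction, so none is given for them. Each of the 4 probes had an adjusted p of 0.167 in limma and the same sign in all 4 numbers, which was a condition of their choice. They were also picked by the smallest p, so their separate groups follow largely from the choice. Differences picked in this way are likely to be overstated.

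**Figure D3:**
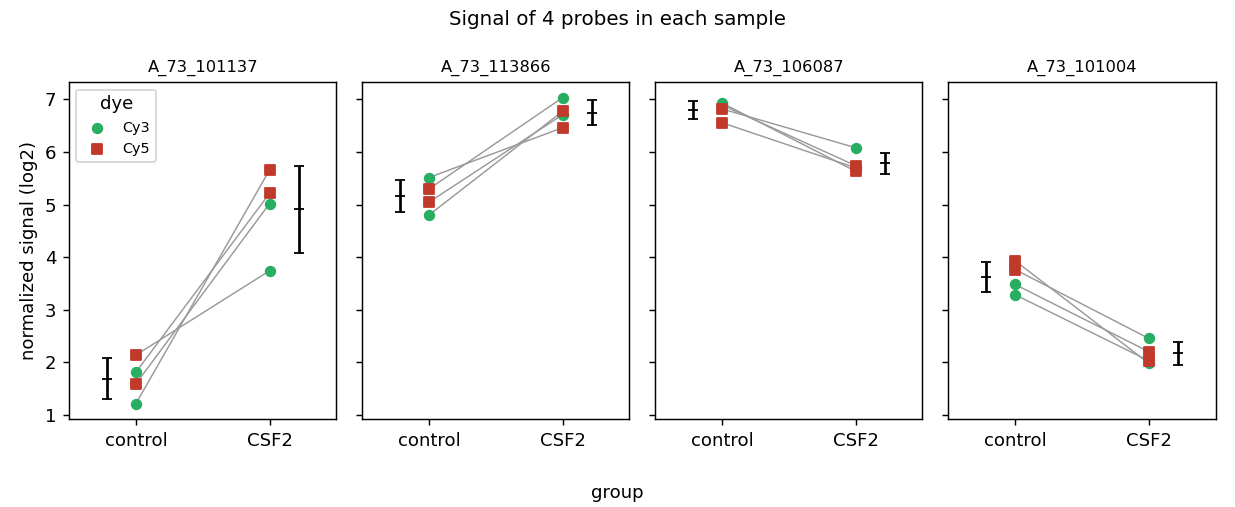
Normalized log2 signal (vertical) of 4 probes in control and CSF2 pools (horizontal); points are samples coloured and shaped by dye, grey lines join the pools of a number, and black bars are the mean ± SD of 4 pools. In each probe the 4 CSF2 pools lie on one side of the 4 control pools, which follows largely from picking the smallest p. No probe passed the adjusted threshold (adjusted p = 0.167, limma).

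The dyes, which were balanced over treatment, were compared in the same fit. No probe differed between Cy5 and Cy3 at an adjusted p under 0.05 in limma, with a lowest adjusted p of 0.122. At an unadjusted p under 0.05 there were 2163 probes (10.1%), where a 5% share would be 1074. Without the block on the number there were 1272. Among the 7 assignments of dye within the numbers that could be fitted, the real one gave the most probes, and the others gave 674 to 1633. As 1 of 7 must be highest, this is weak evidence. Of the 2163 probes, 634 differed at least 1.5-fold. Cy5 was higher in 328 of these and lower in 306. The ordinary test per probe called 4 probes for dye, and a robust prior with a trend over signal called 10.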

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

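The alternatives were chosen before the data were examined, apart from those on the bounded probes. In limma, 0 probes differed between CSF2 and control under 23 of 24 alternatives. Without CSF2 replicate 3 the count was 1, a probe outside the 4 named ones, with a difference of -2.31 and an adjusted p of 0.0183, which with all samples had -1.86 (SE 0.35) and an adjusted p of 0.553. The probes at an unadjusted p under 0.05 with at least a 1.5-fold difference, 571 as reported, were 349 with no replicate block and 350 with neither dye term nor replicate block. They were 359 without the lowest quartile of signal, 77 without all probes below the median signal (27 higher and 50 lower), and 348 in the ordinary test per probe. The filters remove probes by construction, and a fit without the block counts the spread between numbers as error. The cause of the other shifts was not tested. The leave-out fits gave 596 to 1207. The probes at an unadjusted p under 0.05, 1795 as reported, were 924 with no replicate block, 906 with neither dye term nor block, 1291 with the block as a fixed term, and 1371 to 3165 in the leave-out fits. The dye count of 0 became 7 without the probes below the median signal, 10 with the trended robust prior, 4 in the ordinary test, and 0 to 1 in the leave-out fits, where control replicate 3, CSF2 replicate 1 and CSF2 replicate 4 each gave 1 when left out. The dye count at an unadjusted p under 0.05, 2163 as reported, was 1272 with no replicate block and 1378 without the probes below the median signal, and 1728 to 2891 in the leave-out fits. Dropping the block changed no other call. The probes bounded within 1.5-fold stayed between 8736 and 12036 under all 24 alternatives. The lowest count came without the probes below the median signal, where only 10737 probes were fitted. Among the alternatives that fitted all 21475 probes the lowest was 9857, without both pools of number 4. The 4 named probes kept their sign in every alternative that held them, and none reached an adjusted p under 0.05, with a lowest value of 0.0758. Quantile normalization, median centring and cyclic loess kept every count within 1.5 times. Probes below the median signal were bounded less often than probes above it, because their intervals were wider. The median interval reached 1.53-fold to either side in the lowest quartile and 1.51-fold in the second. It reached 1.27-fold in the third quartile and 1.16-fold in the highest. The cause of the wider intervals was not tested.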

Other observations

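The split tests below were fixed before their results were seen, except those on the counts of 0, which were already known. None of 16 checks for a sample far from the others of its group (medians, low values, correlations, spread and the 4 named probes) was met. The checks on the named probes say little, since these were picked by the smallest p, which favours pools that lie close together.

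The largest separation of the samples found here lay between numbers. When numbers 1 and 4 were set against numbers 2 and 3, 1641 probes had groups that did not overlap and 24 were at least 2-fold apart without overlap. CSF2 against control gave 606 and 2, both of the 2 higher with CSF2. This arrangement of the numbers was found by going through all 35 splits of the 8 samples. Other pairings of whole numbers gave 752 probes without overlap (1 and 2 against 3 and 4) and 532 (1 and 3 against 2 and 4). The labels do not say what distinguished the numbers. A shared array or hybridisation and a biological difference could not be told apart, and neither was tested.

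None of the counts of probes tested here set CSF2 against control apart from other ways of splitting the samples. The split that equals dye cannot be fitted beside the dye term, which left 34 splits for the fitted counts. At an unadjusted p under 0.05, 4 of the 34 gave at least the 1795 probes of the real split, and the highest other gave 2466, which was numbers 1 and 4 against 2 and 3. With at least a 1.5-fold difference, 19 of the 34 gave as many as the real 571, with a highest other of 1210. Of the 35 splits, 12 had as many probes without overlap as the real 606, and 35 had as many probes at least 2-fold apart as the real 2, with highest others of 1641 and 24. Only 7 of the 34 splits part every pair of a number. The others, which are most of them, keep pools of a number together, which is no fair measure of chance in this design. Against the 34 or 35 splits, chance was not excluded for these counts. As most of these splits also carry the difference between numbers, they could not settle it. The counts of 0 past the adjusted threshold cannot be tested in this way, since each of the 34 splits reaches 0: the highest other count was 1 for CSF2 and 3 for dye. Of the 7 splits that part every pair of a number, which is the fairer comparison, 2 gave at least 1795 probes and 4 gave at least 571, the real split included. Of the 6 others of this kind, 1 reached 606 probes without overlap and 6 reached 2 probes at least 2-fold apart. The other split that reached 1795, which also reached 606, reversed number 4 alone. Several of the 6 likewise keep the real labels in all but 1 number, and so part of any CSF2 response. Those that reversed numbers 2 and 3, or 3 and 4, gave 741 and 1190 probes at an unadjusted p under 0.05. With at least a 1.5-fold difference they gave 417 and 489. So few splits cannot measure chance. With 7 splits the smallest possible share is 1 of 7, so this comparison could not have excluded chance at 0.05.

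The 1795 probes at an unadjusted p under 0.05 exceeded the 1074 of chance, and 2 explanations were weighed. One is technical: the model gives every probe the same block correlation, which could make p-values too small. The 6 other assignments of CSF2 and control within the numbers gave 690 to 2447 probes with a median of 1207, and 2 of them lay below 1074. Unchanged simulated probes that do share one correlation gave 1208, so this median does not decide. The simulated probes were drawn independently of each other, which real probes need not be, so 1208 need not hold for real probes. Several of the 6 assignments also keep the real labels in all but 1 number, and so part of any CSF2 response. Those that reversed numbers 2 and 3, or 3 and 4, gave 741 and 1190. With the number as a fixed term, which needs no common correlation but leaves fewer degrees of freedom, there were 1291 probes. The other is a CSF2 response shared by the numbers: the covariance of the CSF2 minus control differences between numbers, freed of dye, was 0.0077 (log2 squared), above the highest of the 6 other assignments, 0.00524. As 1 of 7 assignments must be highest, this is weak evidence. As a hypothesis it would correspond to a shared response with an SD of 0.0878 on the log2 scale over probes, or 1.67% of the variance of the differences. Both explanations stay open, and so does chance.

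The probes with at least a 1.5-fold difference at any p lay mostly below the median signal, 1626 of 1722 (94.4%). In the 6 other assignments within the numbers the median share was 94.8%. A candidate explanation is the wider spread of dim probes, since assignments that mix CSF2 and control gave shares of 90.8% to 96.9%. Over all 34 splits, which also part whole numbers, the share went down to 83.7%.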
